A study of Mus musculus with 40 samples.

How the data were processed

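Gene expression was measured on Illumina MouseWG-6 BeadChips, on which each probe is a short oligonucleotide carried by many beads, in 40 samples of mouse neural stem cells (NSCs). Per the labels, the cells were isolated at embryonic day 13.5 from the telencephalon of mice that carried floxed Id1 and Id2 alleles, null Id3 alleles and a Cre recombinase fused to the oestrogen receptor at the Rosa26 locus. They were grown on laminin in medium with FGF-2 and EGF at 20 ng/ml each and received 250 nM 4-hydroxytamoxifen (4-OHT), which releases the recombinase, or the ethanol vehicle for 6, 12, 18, 24, 48, 96 or 144 h. Each of the 14 groups of 1 agent and 1 time had 3 arrays, with the replicate letters A, B and C, except the 2 groups at 144 h, which had 2 arrays each (A and C). The labels do not state that the replicates came from separate cultures or animals, so the p-values measure the spread between these samples, which may in part be technical.

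The deposited table holds for every array a non-normalized bead intensity per probe on a linear scale and a detection p-value per probe, both from the GenomeStudio software per the labels. A second set of deposited values is on the log2 scale and was made by the authors from the intensities with the Bioconductor package lumi and quantile normalization. The versions of both programs were not given in the sources used here. The authors' log2 values had a median of 5.34 per array and ranked the probes of every array as the intensities do, with a lowest rank correlation of 0.999973, so they served as an alternative and not as the starting point. Of the 45281 probes, 21 had rows whose fields were out of step with the header. These were left out, and 45260 were used. Of those, 34872 carried 1 gene symbol, 18 several and 10370 none. The symbol and Entrez identifier of 34794 probes were found together in the RefSeq table for the mouse genome build GRCm38.p6, which changed 0 symbols. Probe positions were not used.

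Intensities were corrected for background and normalized with the function neqc of limma 3.58.1 under R 4.3.3. It fits a normal and an exponential component, taking the background from the detection p-values, adds an offset of 16, applies quantile normalization over the 40 arrays and takes log2. Probes with a detection p-value under 0.01 on at least 3 arrays were tested. This kept 21740 probes, of which 18353 carried 1 symbol, for 11087 genes. The median raw intensity per array ran from 32.2 to 51.1. On 39 arrays between 15884 and 19186 probes were detected. The vehicle array of replicate C at 6 h was dim: 12947 probes were detected on it, and its 95th percentile of intensity was 125 against 547 to 1531 on the others. It was kept, and all results were recomputed without it. The number of arrays limits the precision of every value. The highest correlation between 2 arrays of a group was 0.997, and no 2 arrays held identical values.

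A linear model with 1 mean per group was fitted to all 40 arrays with limma, with moderated variances that follow a trend with intensity. It had 26 residual degrees of freedom and a median of 6.79 prior degrees of freedom. At each time 4-OHT was compared with the vehicle arrays of that time, so no vehicle array served at more than 1 time. All tests were two-sided, with Benjamini-Hochberg adjustment over the probes of a comparison, and a probe was called at an adjusted p under 0.05. Moderated F tests asked whether 4-OHT and vehicle differed at any time, whether the effect differed between times, and whether vehicle changed between 18 and 144 h. A further contrast took the mean effect at 96 and 144 h minus that at 6 and 12 h. Values are log2 differences, 4-OHT minus vehicle, with the model's standard error (SE). Group levels are means with SD on the log2 scale. Where the detection p-value was 0.05 or more on every array of a group, the fold is given as a lower bound, for which the level on each array of that group was set to the lowest level of any probe detected on that array, or to the probe's own level where that was higher.

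Array numbers in the labels fall into 3 series, called runs here, and the labels do not state whether they are hybridization batches or only sample numbers: 1 with replicates A and B at 18 to 144 h, 1 with replicate C at 18 to 144 h, and 1 with all arrays of 6 and 12 h. A difference between runs that adds the same amount to both agents cancels in each comparison, but it widens the spread within a group. Whether the letters pair a 4-OHT array with a vehicle array was checked by correlating residuals over probes. At 18, 24, 48 and 96 h the correlations between arrays of the same letter ran from 0.368 to 0.783. The own letter was the best match at each of these times for C, but only at 24 h for A and only at 96 h for B. These values therefore do not tell a pairing by letter from a difference between the array runs. At 6 h they were 0.116, -0.0445 and 0.00852, and at 12 h 0.421, 0.185 and -0.143. At 144 h the 2 pairs gave 0.671, which 2 arrays per group fix at a single value. The letter was therefore used as a block only as an alternative, and its values stand beside the results it moved.

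The following choices were made before the data were examined: the tests, the threshold, the alternatives except 5, 28 gene lists, and the rule for the genes named. The rule takes Id1, Id2, Id3, Id4 and Rap1gap at every time. It takes up to 12 genes up and 12 down at each time from 18 h, and up to 6 each way at 6 and 12 h, with the largest absolute change among called probes of 1 symbol for which every 4-OHT array lay above, or below, every vehicle array. It also takes up to 4 members with the smallest p of each list spoken of. Where another gene is named, it was chosen after its values were seen. Of the 28 lists, 26 had at least 5 measured genes, each represented by its probe with the highest mean, and were tested with camera of limma at a preset correlation between genes of 0.01. The 182 tests, for 26 lists at 7 times, were adjusted together. Because genes of a list move together, each test was repeated with the correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes.

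The alternatives were no background correction, an offset of 50, scaling by the median in place of quantiles, the authors' log2 values, no filter, detection on at least 20 arrays (17656 probes), 1 probe per gene, variances without the trend or estimated robustly, weights per array, the replicate letter or the array run as a block, the first array run alone, each time fitted alone, a fold of at least 1.5 besides the threshold, and each array left out in turn. The steps were also tested on simulated data, in which 200 of 21740 probes were changed in 1 comparison. At a log2 size of 1 the test recovered 65% at 6 h, 64% at 48 h and 45% at 144 h, and at a log2 size of 2 it recovered 99%, 97% and 95%. The share of false calls was 6.29%, 5.29% and 3.45%. The simulated noise was independent between probes and between arrays, with 1 variance per probe. It lacked the differences between array runs and single arrays of the real data, so these rates may not hold there. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.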

Results

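Transcript levels were measured on 40 arrays of mouse neural stem cells, in 7 pairs of groups that received 4-OHT or vehicle for 6, 12, 18, 24, 48, 96 or 144 h. Each group had 3 arrays, and each of the 2 groups at 144 h had 2. Between 12947 and 19186 probes were detected per array, and 21740 were tested. The first principal component held 27.1% of the variance. Every gene named below as risen or fallen lay, on all 4-OHT arrays of that time, above or below all vehicle arrays of that time, except the members of gene lists, for which this was not required. Positions on the genome were not used.

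The first question was when the transcripts of the floxed genes disappear. Id2, whose product binds basic helix-loop-helix (bHLH) proteins and keeps them from DNA, fell by 18 h (probe ILMN_1228557). Its level was 7.27 ± 0.44 with 4-OHT and 9.28 ± 0.25 with vehicle (log2, mean ± SD, n = 3 each), 4.02-fold lower (adjusted p = 1.02e-05). The difference was -2.76 ± 0.24 (SE) at 24 h, -4.25 at 48 h, -4.94 at 96 h and -5.27 ± 0.29 at 144 h, where Id2 was 38.5-fold lower (n = 2 each, adjusted p = 2.5e-14). At 6 h it was -0.56 ± 0.24 (adjusted p = 0.699) and at 12 h -1.21 ± 0.24 (adjusted p = 0.289), so neither passed, although at 12 h all 4-OHT arrays (7.68 to 8.08) lay below all vehicle arrays (8.85 to 9.43). Id1, a gene of the same family, showed differences of 0.21, -0.09, -0.63 and -0.94 ± 0.26 at 6, 12, 18 and 24 h (adjusted p = 0.161 at 24 h). It fell by 1.87 ± 0.26 at 48 h (adjusted p = 3.12e-05). At 96 and 144 h Id1 was not detected on any 4-OHT array, and was at least 24.2-fold and at least 23.8-fold lower (adjusted p = 5.33e-15 and 1.51e-12). Id1 with vehicle was 6.89 ± 0.32 at 18 h and 9.04 ± 0.34 at 144 h. A second Id2 probe (ILMN_2887239) fell by 1.53 at 18 h (adjusted p = 0.0092). The third (ILMN_1236868) was first called at 48 h, with -1.73 (adjusted p = 0.0439), where the 4-OHT arrays of replicates A and B read 5.01 and 4.69 and that of replicate C 7.56. From 6 to 24 h its differences were positive (0.68, 0.31, 0.64 and 0.14), against those of the first probe, and not called. At 18 and 24 h they rested on 4-OHT replicate C (8.87 and 8.30), as A and B differed by 0.11 and 0.05 at 18 h and by -0.29 and -0.31 at 24 h. Where the probes lie relative to the floxed exons was not examined. Id3, null in these mice per the labels, stayed under the filter with group means of 4.38 to 4.66. At 12 h Id2 passed with the array run as a block (adjusted p = 0.0146) and without vehicle replicate B (-1.31, adjusted p = 0.0238). At 24 h Id1 passed with the replicate letter as a block (-0.94, adjusted p = 0.0391) and in the first array run alone (-1.17, adjusted p = 2.64e-05). With each time fitted alone Id2 missed the threshold at 18 h (adjusted p = 0.252), Id1 at 48 h (0.0534) and both at 144 h (0.0638). Scaling by the median, which moved the median of all probes by 0.34 at 6 h and by -0.11 at 144 h, gave Id2 0.11 at 6 h and an adjusted p of 0.0911 at 18 h.

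Id4, the family member left intact, rose from 18 h on. The difference was 1.61 ± 0.25 (adjusted p = 0.000938) at 18 h, 1.98 at 24 h, 2.94 at 48 h, 3.32 at 96 h and 3.25 ± 0.30 at 144 h. At 96 h Id4 was 8.13 ± 0.19 with 4-OHT and 4.81 ± 0.26 with vehicle, 9.99-fold higher (adjusted p = 2.54e-11). Rap1gap, which encodes a GTPase-activating protein that switches RAP1 off, rose by 1.68 ± 0.28 at 18 h (adjusted p = 0.00285), 1.82 at 24 h, 1.84 at 48 h, 2.16 at 96 h and 2.84 ± 0.34 at 144 h. At 144 h it was 10.47 ± 0.20 against 7.63 ± 0.31, 7.16-fold higher (adjusted p = 6.82e-07). Of 3 further Rap1gap probes, ILMN_1244585 was called higher from 24 h (0.84), ILMN_2942117 from 48 h (1.05) and ILMN_2423853 was not tested, and the second probe of Id4 was called higher from 48 h. At 6 and 12 h the differences were 0.07 and 0.83 for Id4 and 0.50 and 0.74 for Rap1gap, and none passed. Without 4-OHT replicate B at 18 h Rap1gap had a difference of 1.58 and an adjusted p of 0.0608.

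**Figure D1:**
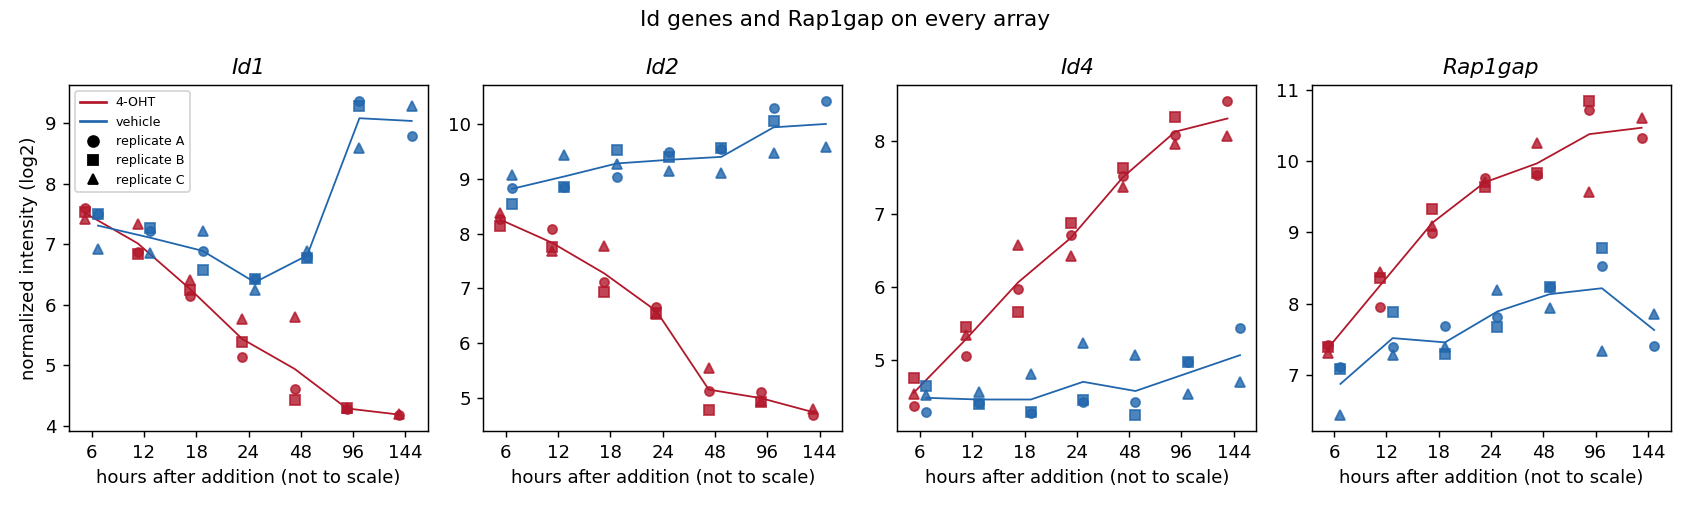
Normalized log2 intensity of Id1, Id2, Id4 and Rap1gap (probes ILMN_2672190, ILMN_1228557, ILMN_2678714 and ILMN_1227577) against hours after addition, not to scale, with a point per array shaped by replicate letter and lines through the means of 4-OHT (red) and vehicle (blue). Id2 ended at 4.74 with 4-OHT against 10.01 with vehicle at 144 h, and Id4 at 8.32 against 5.06.

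At 6 and 12 h the comparison asked for the earliest changes. Genes of cholesterol synthesis lay lower as a group with 4-OHT at 6 h, with a negative difference in 19 of the 21 measured, although their median was 0.44 under median scaling. Among them were Dhcr7 (-0.84), Cyp51 (-0.36), Srebf2 (-0.34) and Sqle (-0.24), and the median was -0.18 (adjusted p = 0.000807; adjusted p = 0.419 with an estimated correlation). At 12 h their median was -0.10, with Dhcr7 at -1.08 and Sqle at -0.41 (adjusted p = 0.0146; 0.621 with an estimated correlation). The list of FGF and ERK feedback genes holds targets of growth factor signalling and also receptors such as Egfr. Its median was -0.10 at 6 h, or 0.40 under median scaling, with Spry4 at -0.62 and Lif at -0.51 (adjusted p = 0.0123; 0.261 with an estimated correlation). At 12 h it was -0.22, with Spred2 at -0.94, Dusp4 at -0.59 and Etv5 at -0.46 (adjusted p = 0.000715; 0.145 with an estimated correlation). No member of either list was called among all probes. Adjusted over the list alone, 0 were called in either list at 6 h, and 1 FGF and ERK feedback gene was lower at 12 h. With limma 0 of 21740 probes were called at 6 h and 0 at 12 h, where 1482 and 1105 had an unadjusted p under 0.05 against 1087 expected by chance. The replicate block gave 0 and 5, the array run as a block 8 at 12 h, array weights 674 at 12 h, a random effect of the block 6 and 12, no filter 4 at 12 h, and each time fitted alone 0 (1287 at an unadjusted p under 0.05) and 1. Without vehicle replicate A 196 were called at 6 h, where replicate B and the dim replicate C then made up the vehicle group. Without vehicle replicate B 71 were called at 12 h. The cholesterol list lost its call under median scaling at 6 h (adjusted p = 0.801) and at 12 h (0.132). At 12 h it also lost it without 4-OHT replicate A (0.0533), vehicle replicate B (0.0638) or vehicle replicate C (0.0511). The FGF and ERK list at 6 h lost it under median scaling (0.817) and without vehicle replicate C (0.319), an array with few detected probes.

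At 18 h 16 probes were called, 11 up and 5 down, and 14 named genes follow from them. Besides Id4 and Rap1gap, Kank1, an adaptor that restrains actin assembly, rose to 8.97 ± 0.34 from 7.62 ± 0.14 (2.55-fold, n = 3 each, adjusted p = 3.99e-05). Ftdc1 was at least 3.41-fold higher. Tafa4 (1.86), Rasl12 (1.86), Tmem255b (1.24), Prkcq (1.24), Irf4 (1.18) and Mfsd6 (1.08) rose, with adjusted p from 2.14e-06 to 0.0436. With Id2, Hs3st1, an enzyme that sulfates heparan sulfate, fell by 1.72, Vegfc, a growth factor, by 1.23 and Dusp4, a phosphatase induced by ERK, by 0.88 ± 0.16 (adjusted p = 0.0104). Id2, Id4, Kank1, Ftdc1 and Tmem255b kept their call whichever array was left out. Hs3st1 and Dusp4 lost it without any 1 of the 6 arrays (adjusted p up to 0.321 and 0.0943) and Tafa4 without any but vehicle replicate B (up to 0.661). Rasl12 lost it without B of either agent, 4-OHT A or vehicle C (up to 0.301), Mfsd6 without B of either, vehicle A or 4-OHT C (up to 0.091) and Irf4 without 4-OHT A or B or vehicle A (up to 0.0923). Vegfc lost it without 4-OHT B or vehicle C (up to 0.0791), Rap1gap without 4-OHT B (0.0608) and Prkcq without 4-OHT C (0.0631). Immediate early genes had a median of -0.20, with Klf2 (-0.83), Klf6 (-0.76), Junb (-0.75) and Dusp1 (-0.56), and 0 of 24 called, 1 lower adjusted over the list alone (adjusted p = 0.000225; 0.145 with an estimated correlation). FGF and ERK feedback genes had a median of -0.19, with Dusp4 the 1 of 21 called, also adjusted over the list alone (adjusted p = 0.00819; 0.209 with an estimated correlation). Oligodendrocyte lineage genes had a median of 0.17 with 0 of 23 called, 2 higher adjusted over the list alone (adjusted p = 0.00046; 0.562 with an estimated correlation). The 42 genes of G2 and M phase had a median of 0.13 with 0 called, also adjusted over the list alone (adjusted p = 0.0232; 0.956 with an estimated correlation). The immediate early and the FGF and ERK lists lost the call without replicate C of 4-OHT (0.118 and 0.172) or of vehicle (0.0796 and 0.0633) and in the first array run alone (0.478 and 0.231). The oligodendrocyte list lost it without 4-OHT replicate C (median -0.01, 0.179), and the G2 and M list without 4-OHT replicates A (0.137) or B (0.257) or vehicle replicate C (0.992) and in the first run alone (0.0661). At 18 h 642 probes had an unadjusted p under 0.05, fewer than the 1087 expected by chance. The replicate block called 139 probes (51.1% up against 68.8%), the array run as a block 180, the first run alone 666 and median scaling 4. Fitted alone, the 6 arrays gave 0 (502 at an unadjusted p under 0.05). Leaving out 4-OHT replicate A or vehicle replicate A gave 10 each, 4-OHT replicate B 6, and both arrays of A, B or C 6, 6 or 10.

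At 24 h 54 probes were called, 42 up and 12 down, and 41 genes. Gpr17, a receptor of oligodendrocyte precursors on their way to myelination, was 5.87-fold higher (9.52 ± 0.58 against 6.96 ± 0.72, n = 3 each, adjusted p = 0.00922). Ftdc1 was at least 8.52-fold and Syndig1l at least 4.41-fold higher. Dpp10, which modulates potassium channels (2.22), Rasl12 (2.19), Tafa4 (2.18), Lims2 (2.16), Irf4 (2.07), Kank1 (1.97 ± 0.18) and Adamts16 (1.89) rose with Id4 and Rap1gap. Hs3st1 (-1.55), Syt1, the calcium sensor of transmitter release (-1.40), Nuak2 (-1.22), Lhfp (-1.09), Dusp4 (-1.05), Ctsc (-0.94), Vegfc (-0.93), Otx2 (-0.89) and Ext1 (-0.59) fell with Id2. Of 23 oligodendrocyte lineage genes 2 rose, Gpr17 and Cnp, a protein of myelin-forming cells (1.79), and 3 adjusted over the list alone (median 0.42, adjusted p = 1.77e-07; 0.27 with an estimated correlation). Of 15 BMP and TGF-beta response genes Id4 and Bmp7 (0.98) rose and 13 were not called, 3 adjusted over the list alone (median 0.14, adjusted p = 0.00301; 0.145 with an estimated correlation). Of 21 FGF and ERK feedback genes Dusp4 fell, and Etv5 had -0.66, with 2 lower adjusted over the list alone (median -0.09, adjusted p = 0.0123; 0.261 with an estimated correlation). Neither the 26 hypoxia and glycolysis genes, with Adm at 0.71 (median 0.23, adjusted p = 0.0372; 0.901 with an estimated correlation), nor the 8 targets of the AhR and oestrogen receptors (median -0.42, adjusted p = 0.0367; 0.152 with an estimated correlation) had a member called, 0 adjusted over the list alone in either. The AhR and oestrogen receptor list lost its call without vehicle replicates A (0.289) or B (0.0595) or 4-OHT replicate C (0.387), and the hypoxia list without 4-OHT replicates A (0.282) or B (0.529) or vehicle replicate C (0.51). The FGF and ERK list lost it without 4-OHT replicate A (0.114) or vehicle replicate C (0.136) and under median scaling (0.105), and the BMP list in the first array run alone (0.139). Of 22 genes from the call rule, Id2, Id4, Rap1gap, Ftdc1, Syndig1l, Rasl12, Irf4, Kank1, Syt1 and Dusp4 kept their call whichever array was left out. Otx2 and Ext1 lost it without any 1 of the 6 arrays (adjusted p up to 0.226 and 0.294), Ctsc without any but vehicle C (up to 0.304), and Hs3st1 (up to 0.396), Nuak2 (0.16), Lhfp (0.167) and Vegfc (0.245) without any but 4-OHT C. Lims2 lost it without A of either agent, vehicle B or 4-OHT C (up to 0.205) and Adamts16 without A of either, 4-OHT B or vehicle C (up to 0.171). Dpp10 lost it without 4-OHT A or B or vehicle C (up to 0.148), Gpr17 without vehicle A or B or 4-OHT C (up to 0.127), Tafa4 without vehicle C (0.0692) and Bmp7 without 4-OHT B (0.0571) or vehicle A (0.124). At 24 h 824 probes had an unadjusted p under 0.05, fewer than the 1087 expected by chance. The replicate block called 326 probes (58.9% up against 77.8%), the array run as a block 384, the first run alone 1172, median scaling 32 and the 6 arrays alone 19. Leaving out replicate A or B of 4-OHT gave 34 and 29, of vehicle 28 each, and both arrays of A or B 21 and 19.

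At 48 h 207 probes were called, 141 up and 66 down, for 144 genes, and 101 rose and 40 fell by more than 2-fold. Dpp10 was 9.24 ± 0.54 against 5.83 ± 0.69, 10.7-fold higher (n = 3 each, adjusted p = 5.99e-06). Syndig1l (8.52-fold), Ftdc1 (8.22-fold), Id4 (7.66-fold), Adamts16 (6.9-fold), Tafa4 (6.49-fold), Gpr17 (6.39-fold), Ptpre (5.28-fold), Cdkn1c, an inhibitor of cyclin-dependent kinases (4.77-fold), Col18a1 (4.76-fold), Slc24a3 (4.28-fold) and Igfbp5 (4.21-fold) were also higher. With Id2 and Id1, Socs2, an inhibitor of cytokine signalling (-1.90), Hopx (-1.85), Sez6 (-1.79), Grm5, a glutamate receptor (-1.73), Igfbp4 (-1.57), Ednrb, an endothelin receptor (-1.56 ± 0.27), Ctsc (-1.55), Hs3st1 (-1.55), Rerg (-1.49) and Rab3b (-1.49) fell, with adjusted p from 4.33e-05 to 0.029. Oligodendrocyte lineage genes rose in 4 of 23, Cnp (1.64), Bcas1 (1.05), Gpr17 and C1ql1 (at least 2.46-fold), and in 8 adjusted over the list alone (median 0.65, adjusted p = 7.68e-14; 0.145 with an estimated correlation). In the BMP and TGF-beta list Id4 and Bmp7 (1.19) rose, 2 of 15, also adjusted over the list alone (median 0.08, adjusted p = 0.00302; 0.145 with an estimated correlation). Of 10 ependymal and choroid markers Otx2 fell by 0.88 and 9 were not called, also adjusted over the list alone (median -0.18, adjusted p = 0.00819; 0.145 with an estimated correlation). That list lost its call without vehicle replicate C (0.0523) and in the first array run alone (0.0543). Of 24 genes from the call rule 16 kept their call whichever array was left out. Igfbp5 lost it without any 1 of the 6 arrays (adjusted p up to 0.238), and Cdkn1c (up to 0.14) and Sez6 (up to 0.238) without any but 4-OHT C. Socs2 (up to 0.275) and Rerg (up to 0.145) lost it without B of either agent, 4-OHT A or vehicle C, and Ptpre without B of either, vehicle A or 4-OHT C (up to 0.156). Hs3st1 lost it without 4-OHT A or B or vehicle C (up to 0.186), Rab3b without vehicle C (0.1) and Otx2 without vehicle B (0.0768), 4-OHT C (0.126) or vehicle C (0.0924). At 48 h 1357 had an unadjusted p under 0.05. The replicate block called 761 probes (50.2% up against 68.1%), the array run as a block 863, the first run alone 1814, and median scaling 109, 92.7% of them up. Leaving out replicate A or B gave 125 each for 4-OHT, 137 and 127 for vehicle and 79 and 84 for both arrays, and leaving out both of C 127.

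At 96 h 979 probes were called, 523 up and 456 down, for 686 genes. Dpp10 (17.7-fold), Tafa4 (15.1-fold), Gpr17 (13.4-fold; 11.25 ± 0.67 against 7.5 ± 0.99, n = 3 each, adjusted p = 4.04e-06), Ftdc1 (at least 11.3-fold), Enpp6, a phosphodiesterase of newly forming oligodendrocytes (11.4-fold), Lims2 (10.8-fold), Id4, Slc24a3 (7.99-fold), Pstpip2 (6.98-fold) and Ptpre (6.31-fold) were higher. Gal3st1 and Fa2h, which encode enzymes of lipid metabolism, were 8.28-fold and 6.75-fold higher (adjusted p = 3.24e-07 and 0.000227). With Id2 and Id1, Cntnap4 (-3.05 ± 0.37), Car3 (-2.97), Timp4, an inhibitor of metalloproteinases (-2.61), Cbs, an enzyme of sulfur amino acid metabolism (-2.49), Thrsp (-2.31), Rerg (-2.28), Gdpd2 (-2.24), Diras2 (-2.21) and Hs3st1 (-2.19) fell, and Lcn2, a secreted lipocalin, was at least 5.58-fold lower. Of these 24 genes all but 3 kept their call whichever array was left out. Car3 lost it without 4-OHT A or B or vehicle C (adjusted p up to 0.0711), Lcn2 without any array but vehicle B (up to 0.249, with -1.85 without vehicle C) and Diras2 without A of either agent, vehicle B or 4-OHT C (up to 0.184, with -1.68 without vehicle B). Leaving out 1 array moved the fold of some by more than 1.5 times: without 4-OHT C Fa2h had 3.82, Car3 -3.77 and Timp4 -1.96, and without vehicle C Ptpre had 1.995 (adjusted p = 0.0271), Cntnap4 -3.65, Timp4 -3.40 and Diras2 -3.06. Of 2905 probes with an unadjusted p under 0.05, 1087 were expected by chance. The replicate block called 2540 (45.9% up against 53.4%), the array run as a block 2643, the first run alone 4429, median scaling 453 (68.2% up) and the 6 arrays alone 502. Without replicate A or B of 4-OHT 613 and 571 were called, and without both arrays of A or B 385 and 378.

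At 144 h, with 2 arrays a group, 1438 probes were called, 742 up and 696 down, for 999 genes, and 505 rose and 458 fell by more than 2-fold. Gpr17 was 37.7-fold (11.85 ± 0.63 against 6.61 ± 2.03, adjusted p = 3.28e-07), Enpp6 34.4-fold, Tafa4 31.5-fold, Dpp10 24-fold, Lims2 15-fold, Gpr149 13.4-fold and Vxn 13-fold higher. Tafa4 with vehicle was lower at 144 h than at 18 h (-2.995), so part of its fold at 144 h is a fall in vehicle. Sox10, a transcription factor of the oligodendrocyte lineage, was 18.5-fold higher (adjusted p = 0.000303). Fa2h (14.6-fold), Ugt8a (14-fold) and Gal3st1 (12.5-fold) were also higher, and Mag, a glycoprotein of myelin, was at least 11.4-fold higher. With Id2 and Id1, Lcn2 (-4.36), Chchd10 (-3.45), Timp4 (-3.16), Tslp, a cytokine (-2.94), Cntnap4 (-2.83), Fcgrt (-2.71), Atp1b1 (-2.63), Nupr1, a stress-induced chromatin protein (-2.63), Efhd1 (-2.61) and Palmd (-2.54) fell, with adjusted p from 8.73e-08 to 0.0259. Lcn2 with vehicle was 9.17 ± 4.74. Its difference was -1.01 without vehicle replicate C (adjusted p = 0.306), -7.71 without vehicle replicate A and -3.72 without 4-OHT replicate A (0.0587) and -4.99 without 4-OHT replicate C, and that of Nupr1 -1.18 without vehicle replicate C (0.0149) and -4.08 without vehicle replicate A. Chchd10 and Atp1b1 lost their call without any array but vehicle C (adjusted p up to 0.144 and 0.156) and Palmd without 4-OHT A (-2.03, 0.0979), and the other 20 of the 24 genes kept theirs. Leaving out 1 array moved further folds by more than 1.5 times, in Gpr17 (3.80 to 6.67), Enpp6 (4.47 to 5.74), Tafa4 (4.31 to 5.64), Sox10 (3.54 to 4.89), Mag (2.84 to 4.45, from a vehicle level under detection) and Tslp (-3.58 to -2.30). The replicate block called 3550 probes (47.8% up against 51.6%), the array run as a block 3661, median scaling 763 and array weights, which cannot differ within a group of 2, 360. Unadjusted, 3632 probes had a p under 0.05. Fitted alone, the 4 arrays gave 0 with a smallest adjusted p of 0.0638 (1831 at an unadjusted p under 0.05). Leaving out both arrays of A or C gave 527 and 882, 4-OHT replicate A 866.

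**Figure D2:**
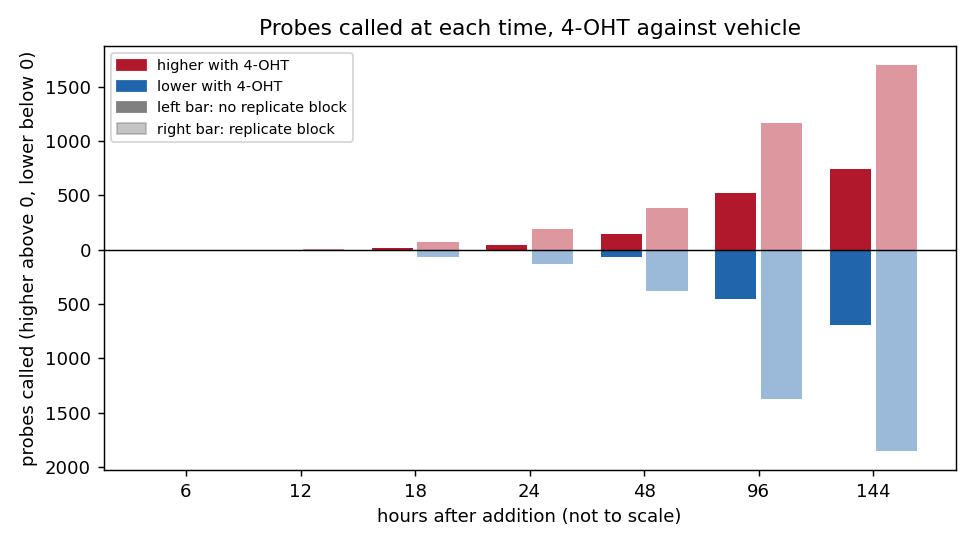
Number of probes called at an adjusted p under 0.05 at each time (not to scale), higher with 4-OHT above 0 and lower below it, with the left bar for the model without a block and the pale right bar for the replicate block. Without the block the counts were 0 at 6 and 12 h, 523 up and 456 down at 96 h and 742 up and 696 down at 144 h, and with it 2540 in all at 96 h and 3550 at 144 h.

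The labels give the cells as neural stem cells, and markers of the lineages they can form were compared at 96 and 144 h. Of 23 oligodendrocyte lineage genes 15 rose at 96 h and 17 at 144 h, none fell, and 20 rose at each time adjusted over the list alone. Their median difference was 1.70 and 2.73 (adjusted p = 6.41e-29 and 8.74e-29; 0.00943 at both times with an estimated correlation), and C1ql1 (2.05 and 2.57), Ugt8a (2.37 and 3.81), Bcas1 (1.66 and 2.86) and Cnp (2.56 and 3.05) rose at both. Olig2, a transcription factor of the lineage, had 0.89 and 1.41 and was not called. By array run the median was 0.13 in replicates A and B and 0.33 in C at 18 h, 0.35 and 0.36 at 24 h and 0.45 and 0.91 at 48 h. At 96 h it was 1.99 in replicates A and B and 1.12 in C, and at 144 h 2.77 in A and 2.47 in C. Of 25 astrocyte markers 5 fell and 3 rose at each time, and 7 and 11 fell adjusted over the list alone, with 3 risen. Gja1, a gap junction protein (-1.44 and -1.36), Slc1a3, a glutamate transporter (-1.21 and -1.16), and Acsbg1 (-2.13 and -1.83) fell, while Id4, a member of that list, rose (medians -0.63 and -1.07, adjusted p = 0.0106 and 0.0121; 0.621 and 0.631 with an estimated correlation). Of 24 neuronal markers 5 rose at 144 h and 19 were not called, 6 adjusted over the list alone, among them Dcx (1.98), Stmn3 (1.61), Syp (1.17) and Map2 (0.61) (median 0.70, adjusted p = 0.0146; 0.332 with an estimated correlation). At 96 h 0 neuronal markers rose and 1 fell, against 2 up and 2 down adjusted over the list alone (median 0.28, adjusted p = 0.146). Of 10 ependymal and choroid markers Otx2 fell by 1.54 at 96 h, also adjusted over the list alone (median -0.39, adjusted p = 0.0123; 0.152 with an estimated correlation). The astrocyte list lost its call at 96 h without 4-OHT replicate C (0.0676) and at 144 h without 4-OHT replicate A (0.0584) or vehicle replicate A (0.148). The ependymal list lost it without vehicle replicate C (0.0628), and the neuronal list without 4-OHT replicate A (0.285) or vehicle replicate A (0.22). At 144 h, without 4-OHT replicate A, Dcx (0.169), Stmn3 (0.0658), Map2 (0.444), Syp (0.123), Gja1 (0.0839), Slc1a3 (0.0963) and Acsbg1 (0.303) were not called. Nor were Stmn3 (0.551), Map2 (0.142) and Syp (0.341) without vehicle A, Stmn3 (0.191) and Syp (0.167) without 4-OHT C, or Map2 (0.0817) and Acsbg1 (0.0867) without vehicle C.

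**Figure D3:**
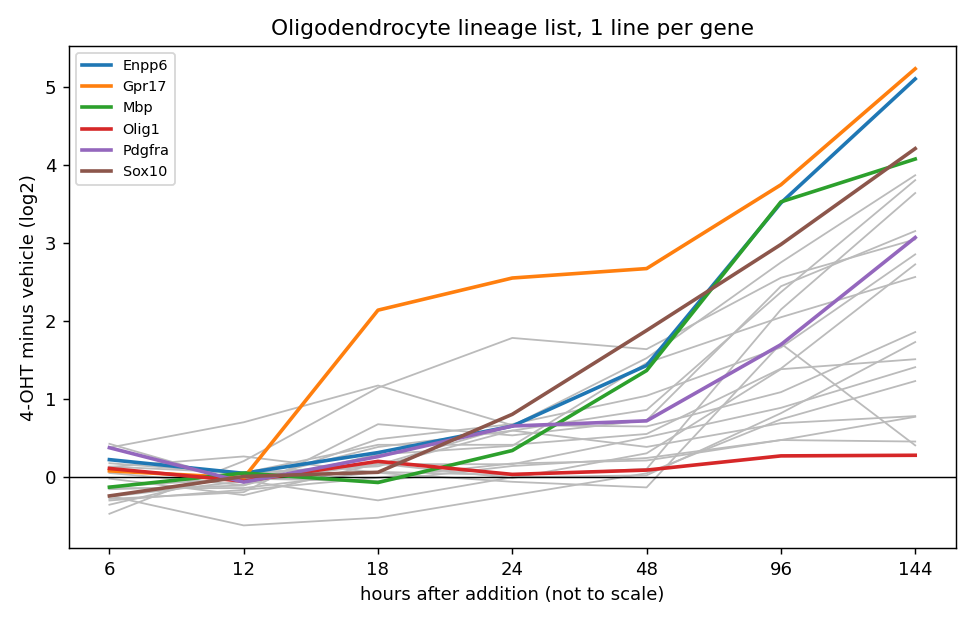
Log2 difference, 4-OHT minus vehicle, of each of the 23 measured oligodendrocyte lineage genes against hours after addition (not to scale), with a line per gene, 6 in colour and the others in grey. At 144 h Gpr17 was at 5.24, Enpp6 at 5.11, Sox10 at 4.21, Mbp at 4.08, Pdgfra at 3.07 and Olig1, which was not called, at 0.28.

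Genes of growth factor signalling, growth and stress were compared at the same late times. Of 21 FGF and ERK feedback genes 4 fell and 1 rose at 96 h and at 144 h, against 5 down and 1 up and 10 down and 2 up adjusted over the list alone. Dusp4 (-0.96 and -1.68), Egfr, the EGF receptor (-1.07 and -1.20), and Etv4 (-1.08 and -1.41) fell at both times and Ier3 (-1.81) at 96 h. In that list Phlda1 (1.42) rose at 96 h and Etv1 (1.06) at 144 h (medians -0.25 and -0.55, adjusted p = 0.0146 and 0.00319; 0.27 and 0.152 with an estimated correlation). Of 26 hypoxia and glycolysis genes Aldoc (-0.83) and Car9 (-0.98) fell at 96 h, also adjusted over the list alone (median -0.42, adjusted p = 0.00301; 0.721 with an estimated correlation). At 144 h 0 of these 26 were called (median -0.008, adjusted p = 0.845). Of 39 S phase genes the replication factors Mcm5 (1.38) and Mcm6 (0.93) rose at 144 h, also adjusted over the list alone (median 0.58, adjusted p = 0.000143; 0.702 with an estimated correlation), whereas at 96 h 1 fell, 0 rose and 9 of the 39 differences were positive (median -0.15, adjusted p = 0.124). Of 42 genes of G2 and M phase 0 were called at 144 h, also adjusted over the list alone (median 0.36, adjusted p = 0.0146; 0.951 with an estimated correlation). Of 31 p53 targets Ccng1 fell by 1.02 at 144 h, also adjusted over the list alone (median -0.40, adjusted p = 0.031; 0.717 with an estimated correlation). The median of the G2 and M list turned to -0.45 without vehicle replicate A (adjusted p = 0.0198) and to -0.32 without 4-OHT replicate C (0.103). The S phase list lost its call without either (0.856 and 0.892), as did Mcm5 (0.838 and 0.436) and Mcm6 (0.493 and 0.2), and Mcm6 without 4-OHT A (0.0801). The p53 list lost its call without 4-OHT replicate A (0.661), without vehicle replicate C (median -0.08 with the test's direction reversed, 0.817) and under median scaling (0.0931). The hypoxia list lost it without vehicle replicates A (0.194) or B (0.132) or 4-OHT replicate C (median 0.01, 0.307), and the FGF and ERK list at 96 h without replicate C of 4-OHT (0.0659) or vehicle (0.0702) and at 144 h without vehicle replicate A (0.0605). At 144 h Egfr (0.32 and 0.255), Etv4 (0.457 and 0.143) and Etv1 (0.169 and 0.1) were not called without 4-OHT A or vehicle C, nor was Ccng1 (0.0692) without 4-OHT A. At 96 h Phlda1 was not called without 4-OHT A (0.0611) or B (0.0581) or vehicle B (0.0656), Aldoc without vehicle A (0.0784) and Car9 without 4-OHT B (0.0703) or C (0.157) or vehicle A (0.185) or B (0.385).

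Comparison of the times asked whether the response grew. The probes called at 18 h were all called at 24 h in the same direction (16 of 16), as were 49 of 54 at 48 h and 186 of 207 from 48 h at 96 h, and 0 in the opposite direction. Of those called at 24 h, 46 were called at 144 h in the same direction and 1 in the opposite one, a Syt1 probe that was lower at 24 h and higher at 144 h. At 96 and 144 h 389 probes were up and 279 down at both, against 17.9 and 14.6 expected by chance, and 0 went opposite ways (r = 0.787 and rho = 0.625 across all probes, which are not independent replicates). The 389 had a median difference of 0.05 at 6 h, 0.06 at 12 h, 0.24 at 18 h, 0.41 at 24 h, 0.58 at 48 h, 1.16 at 96 h and 1.51 at 144 h, and the 279 one of 0.003, -0.10, -0.26, -0.38, -0.58, -1.09 and -1.39. Their choice by calls at 96 and 144 h fixes larger values there, so these medians describe the course and do not test whether it grew. Moderated F tests called 1315 probes for a difference at any time and 394 for an effect that differed between times. The late mean effect minus the early one was called for 1403 probes, 725 more positive and 678 more negative. With the replicate block these 3 counts were 3865, 1772 and 3532, with the array run as a block 3971, 2077 and 3526, and under median scaling 675, 193 and 674. The 668 probes shared by 96 and 144 h became 1767 and 1865 with the blocks, 302 under median scaling, 443 without 4-OHT replicate B at 96 h and 435 without 4-OHT replicate A at 144 h.

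Cells that received vehicle also changed between 18 and 144 h, in 3041 probes by the F test over the times, and the following genes and their values with an array left out were chosen after the results were seen. Tk1 (-3.33), Tyms (-3.19 ± 0.41) and Rrm2 (-2.73), which make DNA precursors, were lower at 144 h. So were the replication factors Mcm5 (-2.75) and Mcm3 (-2.66), and Birc5 (-2.83), of the mitotic spindle. Lcn2 (4.90), Mmd2 (4.46), the chemokine Cxcl1 (4.33), Mylk2 (4.12 ± 0.28), Fcgrt (3.79), Timp1 (3.45) and Tslp (3.37) were higher, with adjusted p from 4.64e-12 to 0.000772 over these 13 genes. Vehicle at 144 h had 2 arrays, and Lcn2 there was 9.17 ± 4.74, so its change was 1.55 without replicate C of that group. The call was lost without 1 array for Cxcl1 (adjusted p = 0.209), Tk1 (0.0785) and Birc5 (0.134). Tafa4, not among these 13, was also lower with vehicle at 144 h (-2.995, adjusted p = 1.38e-05 by limma), which widens its 4-OHT difference there. Of 39 S phase genes 36 fell (median -1.79, adjusted p = 9.3e-36; 0.0384 with an estimated correlation). Of 42 genes of G2 and M phase 37 fell (median -1.70, adjusted p = 9.92e-25; 0.138 with an estimated correlation). Of 28 extracellular matrix genes 12 rose (median 0.98, adjusted p = 3.6e-05; 0.00795 with an estimated correlation). Of 25 astrocyte markers 13 rose (median 1.26, adjusted p = 2.75e-07; 0.17 with an estimated correlation), as did 13 of 26 hypoxia and glycolysis genes (median 1.15, adjusted p = 9.26e-08; 0.353 with an estimated correlation). Of 23 oligodendrocyte lineage genes 1 rose and 1 fell (median 0.17, adjusted p = 0.768). Of 25 interferon genes 10 rose (median 0.80, adjusted p = 9.84e-05; 0.503 with an estimated correlation), among them Gbp2 (3.34) and Usp18 (2.36). Of 21 cholesterol synthesis genes 7 fell (median -0.52, adjusted p = 9.84e-05; 0.261 with an estimated correlation). Of 9 mesenchymal and pericyte markers Myl9 (1.74), Prrx1 (1.31) and Foxc1 (1.1) rose (median 1.1, adjusted p = 0.0458; 0.17 with an estimated correlation). In the Notch list 4 of 20 rose (median 0.23, adjusted p = 0.0458; 0.503 with an estimated correlation), and of 24 immediate early genes 6 rose and 2 fell (median 0.18, adjusted p = 0.0458; 0.407 with an estimated correlation). With an array left out the call was lost for the interferon (0.819), mesenchymal (0.189), Notch (0.18) and immediate early (0.15) lists. The median then ran from -2.29 to -1.36 for S phase, -2.64 to -0.73 for G2 and M phase, 0.72 to 1.59 for hypoxia, 0.12 to 1.64 for interferon and 0.44 to 1.38 for mesenchymal markers. Of the 3041 probes, 461 were also called for a 4-OHT effect at any time. Median scaling called 1301 probes, 1 probe per gene 1893, array weights 11134 and the array run as an additive block 4381. From 18 to 96 h the change in replicate C had a slope of 0.217 on that of A and B over these probes (r = 0.404 across probes).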

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

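The tests of the dim array, of the lag in the loss of Id2, of the ratio of effects between replicates and of all other splits of the arrays were chosen only after the result was seen. The results here stand out because the effect of 4-OHT differed between times by a test of that difference: 394 probes by the F test over the times and 1403 by the mean effect at 96 and 144 h minus that at 6 and 12 h.

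Of the genes named by rule, 54 passed that late minus early test. The rule takes large effects at single times, for many of them 96 or 144 h, which form the late mean. Passing and size were thus in part fixed by the choice, and the values describe these genes only. A change of vehicle cells with time can also enter these values. From 18 to 144 h vehicle changed by -2.995 for Tafa4, 4.90 for Lcn2, 3.37 for Chchd10 and 3.37 for Tslp, each opposite to the late 4-OHT effect. More positive late were Gpr17 at 4.46 (log2), Enpp6 at 4.17, Sox10 at 3.71, Fa2h at 3.46, Gal3st1 at 3.39, Ugt8a at 3.24 and Mag at 3.04. So were Dpp10 (4.39), Lims2 (4.05), Tafa4 (3.92), Ftdc1 (3.55), Vxn (3.06), Slc24a3 (3.01), Gpr149 (2.98), Id4 (2.84), Prkcq (2.61), Tmem255b (2.60) and Syndig1l (2.59). Smaller positive differences were those of Pstpip2 (2.42), Adamts16 (2.11), Kank1 (2.09), Cdkn1c (2.04), Ptpre (1.95), Rap1gap (1.88), Mfsd6 (1.23), Irf4 (1.02) and Syt1 (0.87), which had fallen at 24 h. More negative late were Id1 (-4.88), Id2 (-4.22), Lcn2 (-3.50), Chchd10 (-2.95), Cntnap4 (-2.86), Timp4 (-2.63), Cbs (-2.40), Tslp (-2.38), Palmd (-2.35), Fcgrt (-2.32), Rerg (-2.28), Diras2 (-2.19), Grm5 (-2.05), Thrsp (-2.04) and Hopx (-2.03). Others were Nuak2 (-1.97), Efhd1 (-1.92), Rab3b (-1.89), Sez6 (-1.82), Ctsc (-1.66), Nupr1 (-1.53), Otx2 (-1.52), Ednrb (-1.40), Lhfp (-1.39), Hs3st1 (-1.38), Vegfc (-1.25) and Dusp4 (-0.87). Id1 was not detected on 4-OHT arrays at 96 and 144 h nor Lcn2 at 96 h, so their values are fitted differences without an exact size. The same holds for Ftdc1, Irf4, Mag, Syndig1l and Tmem255b, whose vehicle group was under detection at 96 h, 144 h or both, and for Enpp6, Fa2h, Gal3st1, Gpr149, Gpr17, Lims2, Sox10 and Vxn, with a group under detection at 6 or 12 h. All arrays of 6 and 12 h belong to an array run of their own, so the late minus early difference sets runs as well as times against each other, although a constant difference between runs cancels in each effect.

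At 6 and 12 h no probe was called with limma, with 1482 and 1105 at an unadjusted p under 0.05. The dim vehicle array at 6 h does not account for this, since 0 were called at 6 h without it and after renewed normalization of the other 39. At 12 h the median SD within groups was 1.01 times that at 18 to 96 h, under the bound set beforehand against a wider spread. It was 0.165 with 4-OHT and 0.218 with vehicle. The groups at 18 to 96 h mix array runs and those at 12 h do not, so this ratio cannot exclude a wider spread at 12 h. A lag between the addition of 4-OHT and the loss of the deleted transcripts stays open, since the Id2 difference, 13.2% of that at 48 h at 6 h and 28.5% at 12 h, is itself part of what a lag would explain. The blocks gave at most 6 calls at 6 h and 12 at 12 h. At 12 h 71 were called without vehicle replicate B and 674 with array weights, so the absence of calls there depends on single arrays. At 6 h 196 were called without vehicle replicate A, but vehicle was then replicate B and the dim replicate C alone. As 0 were called without the dim array, the 196 may rest on it.

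The effects of 4-OHT at 144 h tended to run against the change of vehicle cells with time. Vehicle arrays shared by both differences would give such a relation by themselves, yet with no array in common the correlation over probes was still -0.26 (-0.434 among called probes). This lay between the bounds set for and against that explanation, but shared arrays cannot give a value computed without any. How much they add where arrays are shared was not measured. A second explanation is that 4-OHT cultures remained at an earlier point of the vehicle course, and 54.4% of the called probes had a 4-OHT level inside the range of the vehicle means widened by 0.5 log2, again between the bounds set in advance, so this cannot be told apart from a response outside that course for the set as a whole. By direction, 477 of the 742 risen probes lay above the widened range, and 179 of the 696 fallen probes lay below it. An earlier point of the vehicle course does not account for the oligodendrocyte lineage genes, as 0% of the 17 called at 144 h had a level within the widened vehicle range. For that part a response to the loss of Id1 and Id2 may be the cause, as a hypothesis, and an effect of 4-OHT or of the active recombinase itself was not tested, since no group received 4-OHT without the floxed alleles.

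At 48 h the loss of Id1 and of the third Id2 probe was smaller in replicate C, with differences of -1.09 and 0.12 against -2.18 and -2.35 in A and -2.35 and -2.97 in B. To a lesser degree it was also smaller for the first Id2 probe (-3.56 against -4.42 in A and -4.78 in B) and the second (-1.33 against -1.73 in each). If the array numbers of C mark a run that compresses differences, the slope of the vehicle change in C on that in A and B would be low, and its 0.217 met what had been written beforehand, while the ratio of the mean 4-OHT effect in C to that in A and B, over the 979 probes called at 96 h, was 1.11 at 18 h, 0.894 at 24 h and 0.798 at 96 h. These values leave a mild compression open, but not as the whole cause, because at 48 h the ratio was 1.1 (1.09 to A and 1.11 to B alone), against 0.482 for Id1, and a compressed loss of the Id2 probe would still be a loss. A later response in replicate C would raise that ratio from 48 to 96 h, and it changed by -0.302 over the 979 probes. The ratio rose from 0.482 to 0.853 for Id1, from 0.773 to 0.876 for the first Id2 probe and from -0.0441 to 0.751 for the third. For the second Id2 probe it fell from 0.767 to 0.46. A delay of single probes stays open, since Id1 and the third Id2 probe were picked for their low values at 48 h, and no other explanation was tested.

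The 6 arrays of a time can be parted into 3 and 3 in 10 ways, too few for a share under 0.05. The real and the highest other count were 0 and 1 at 6 h, 0 and 336 at 12 h, 16 and 58 at 18 h, 54 and 3 at 24 h, 207 and 0 at 48 h and 979 and 160 at 96 h. As many as the real count came from 10 of the 10 splits at 6 h and at 12 h, 2 at 18 h, and 1, the real one, at 24, 48 and 96 h. At 12 h the split with 336 calls set 4-OHT replicate A and vehicle replicates A and C against the rest, which points to a structure of these samples. At 18 h the split with 58 calls followed the array run, with 4-OHT replicates A and B and vehicle replicate A on a side, and the blocked counts of the real split were 139 by letter and 180 by run. Among the 4 splits that part all 3 pairs of a letter the highest other count was 0 at each of these times. At 144 h the 2 arrays a group were not split.

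For results over all times 100 regroupings were drawn, the real one included, in more than 1 order of the random draws, and both sets are given. With 2 arrays a group at 144 h few groupings of that time exist, so a draw can keep its real labels or swap them whole. Such a draw retains the 144 h effect of 4-OHT. The shares below for any time and for an effect that differed therefore do not measure chance alone. For probes changed at any time, 5 of 100 gave as many as the real 1315 in the first set (highest other 1880) and 2 in the second (1610), so the first set does not exclude chance. Chance was not excluded for the 394 probes whose effect differed between times, with 29 of 100 (1841) and 21 (1451), nor for the 28 list calls, with 6 of 100 (29) and 9 (31). The other regroupings gave a median of 20 list calls in each set. Camera at the preset correlation thus called many lists under regrouped labels too, and its adjusted p values are to be read with that limit. The share was under 0.05 for the 1403 of late against early, with 3 of 100 (1918) and 2 (1575). It was also under 0.05 for the 3041 of the vehicle course, with 3 of 100 (5674) and 1 (2785). Regroupings that parted every pair of a letter from 18 h on, with 6 and 12 h regrouped freely, gave 1 of 100 for any time (highest other 1117). They gave 7 for an effect that differed (1228), 1 for late against early (1260) and 3 for lists (28, with a median of 17). For the vehicle course, times shuffled within a letter gave 1 (2848). For any time and for lists these shares lie under 0.05, so whether chance is excluded there depends on which draws are used, and arrays of the same letter had correlated residuals at 18 to 96 h and not throughout at 6 and 12 h. With the replicate block the counts were 3865 for any time, 1772 for an effect that differed and 3532 for late against early. Because the array runs differ, the free draws include groupings that follow a run.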

How the results depend on the processing

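The vehicle course with the array run as an additive block, the fits without both arrays of a letter, the recomputation without the dim array and the oligodendrocyte list split by replicate letter or without members of other lists were alternatives chosen after seeing the data, and no alternative was left out. Of the counts of probes and lists under settings other than leaving out 1 array, or both of a letter, in turn, 136 stayed within 1.5 times and 67 moved. Those settings include the first array run alone and the fit without the dim array. With arrays left out in turn 264 stayed and 30 moved. Of the named genes, 11613 results kept direction and side of the threshold under the other settings, 702 gained a call and 348 lost it, and with an array left out 4315 kept both, 50 gained a call, 302 lost it and 1 reversed. Of the list results 461 stayed, 72 lost the call and 3 moved, and with an array left out 115 stayed, 36 lost the call and 3 reversed. Signal over background limits Id3 and the levels of genes that fell below detection, such as Id1 from 96 h, to bounds, and 2 arrays a group limit 144 h. Unless a reason is given, the cause was not tested.

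With the replicate letter as a block the calls were 5 at 12 h, 139 at 18 h, 326 at 24 h, 761 at 48 h, 2540 at 96 h and 3550 at 144 h. They were 3865 for any time, 1772 for an effect that differed between times, 3532 for late against early and 1767 shared by 96 and 144 h, and Id1 at 24 h passed (-0.94, adjusted p = 0.0391). With the array run as a block they were 8, 180, 384, 863, 2643 and 3661 from 12 to 144 h, then 3971, 2077, 3526 and 1865, and Id2 at 12 h (-1.21, adjusted p = 0.0146) and Id1 at 24 h (-0.94, adjusted p = 0.0116) passed. With the letter as a random block they were 6 at 6 h, 12, 119, 264, 661, 2378 and 3271 from 12 to 144 h, then 3755, 1647, 3394 and 1611, and Id2 at 12 h (-1.21, adjusted p = 0.0136) and Id1 at 24 h (-0.94, adjusted p = 0.0124) passed. A block removes the spread between letters or runs from the residual. Arrays of the same letter had correlated residuals at 18 to 96 h, but for A and B the own letter was mostly not the best match.

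The first array run alone called 666, 1172, 1814 and 4429 probes at 18, 24, 48 and 96 h, and Id1 at 24 h passed (-1.17, adjusted p = 2.64e-05). Array weights gave 674, 260, 1795, 2828, 4857 and 360 from 12 to 144 h, 6185 for any time, 2864 for an effect that differed, 11134 in vehicle and 348 shared. With them Id2 at 12 h (-1.19, adjusted p = 0.00108) and Id1 at 24 h (-1.06, adjusted p = 1.02e-06) passed. The arrays of replicate C at 18 to 96 h had weights of 0.233 to 0.403 and those of A and B 0.821 to 5.31. At 144 h the weights cannot differ within a group of 2 and were 0.404 and 0.274. Whether this accounts for the lower count of 360 there was not tested.

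Each time fitted alone, with 4 residual degrees of freedom or 2 at 144 h against 26, gave 1 call at 12 h, 0 at 18 h, 19 at 24 h, 502 at 96 h and 0 at 144 h, with 502 and 1831 probes at an unadjusted p under 0.05 at 18 and 144 h by limma. Id2 at 18 h (-2.01, adjusted p = 0.252), Id1 at 48 h (-1.87, 0.0534) and Id1 (-4.85) and Id2 (-5.27) at 144 h (0.0638 each) then missed the threshold. Median scaling gave 4, 32, 109, 453 and 763 from 18 to 144 h, 675 for any time, 193 for an effect that differed, 674 for late against early, 1301 in vehicle and 302 shared, and Id2 at 18 h missed the threshold (-2.12, adjusted p = 0.0911). Without the filter 4 probes were called at 12 h. With 1 probe per gene, and so fewer tests, 946 were called at 144 h, 823 at any time, 919 for late against early and 1893 in vehicle. The vehicle course with the array run as an additive block gave 4381 against 3041. Without the dim array and after renewed normalization the calls were 0, 0, 16, 59, 222, 1031 and 1541, and with the authors' values 0, 0, 17, 54, 195, 1001 and 1440. List calls were 2 of 182 with an estimated correlation and 20 with fry, against 28, and 44 with all probes of each gene.

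With arrays left out 1 at a time, and at a letter where both were left out, the calls ran from 0 to 196 at 6 h, 0 to 71 at 12 h, 6 to 17 at 18 h, 19 to 76 at 24 h, 79 to 195 at 48 h, 378 to 1115 at 96 h and 527 to 1562 at 144 h. They ran from 435 to 746 for those shared by 96 and 144 h, 1059 to 1566 for any time, 290 to 510 for an effect that differed, 1167 to 1621 for late against early and 2332 to 3934 in vehicle. A lone array left in a group at 144 h is assumed to vary like the other groups. Id2 at 12 h ran from -1.33 to -1.02 and passed without vehicle replicate B (-1.31, adjusted p = 0.0238). The 196 calls at 6 h came without vehicle replicate A, with the dim array left in, and the 71 at 12 h without vehicle replicate B. At 144 h the G2 and M phase list, with a median of 0.36, ran from -0.45 to 1.36, with -0.45 without vehicle replicate A (adjusted p = 0.0198) and -0.32 without 4-OHT replicate C (0.103). The p53 list, with a median of -0.40, ran from -0.71 to -0.026 and had -0.08 with the test's direction reversed without vehicle replicate C (0.817). Rtp4, with 1.15, ran from -0.079 without 4-OHT replicate C (0.93) to 2.38.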

Other observations

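All tests in this part were planned. The remaining gene lists were not called by camera at any of the 7 times, and some of their members changed late. In the interferon list (25 genes) Rsad2 rose at 96 and 144 h (2.21 and 2.30), and Mx2 (1.44), Usp18 (1.94) and Rtp4 (1.15) at 144 h, with a smallest list adjusted p of 0.0538 at 144 h. Without vehicle replicate A at 144 h these 4 were not called (adjusted p = 0.0786 for Rsad2, 0.487 for Mx2, 0.723 for Usp18 and 0.371 for Rtp4), nor without 4-OHT C were Mx2 (0.625), Usp18 (0.812) and Rtp4 (-0.08, 0.93). In the Notch list (20 genes, smallest adjusted p = 0.214 at 48 h) the ligands Dll3 (1.55 and 2.10) and Dll1 (0.97 and 1.31) and the glycosyltransferase Mfng (1.61 and 2.28) rose at 96 and 144 h, and the transcription factor Hes6 fell (-0.99 and -0.95). At 96 h Dll3, Mfng and Dll1 were not called without 4-OHT A (0.0578, 0.106 and 0.119) or B (0.0568, 0.0878 and 0.163), nor Mfng (0.0954) and Dll1 (0.327) without vehicle C. At 144 h Dll3 (0.0682) and Dll1 (0.0928) were not called without 4-OHT A, nor Mfng (0.181) and Dll1 (0.258) without vehicle A.

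Of 26 integrated stress response genes 4 fell at 144 h, Nupr1 (-2.63), Cebpb (-2.18), Slc7a11 (-1.89) and Atf5 (-1.50), and Stc2 (-0.98) at 96 h (smallest adjusted p = 0.104 at 144 h). Nupr1 was at -1.18 without vehicle replicate C and -4.08 without vehicle A. Slc7a11 was not called without 4-OHT A (0.208) or vehicle A (0.0611) or C (0.095), Atf5 without vehicle A (0.166) or 4-OHT C (0.355), and Stc2 without any array but vehicle C (up to 0.174). Cdkn1c, a CDK inhibitor, rose at 96 and 144 h (2.52 and 2.87) as the 1 of 16 in the list of CDK inhibitors and pocket proteins (smallest adjusted p = 0.275 at 6 h), though at 144 h not without 4-OHT A (0.115). Rap1gap was the 1 of 17 RAP1 regulators to rise at both times (smallest adjusted p = 0.379 at 144 h), and of 8 bHLH activators 0 were called by limma at either (smallest adjusted p = 0.0555 at 12 h).

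With fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, 20 of the 182 tests passed. The bHLH activators passed at 12 h as lower (median -0.14, adjusted p = 0.0247) and at 48, 96 and 144 h as higher (0.16, 0.17 and 0.20, adjusted p = 0.0269, 0.0118 and 0.00232). With bounds for members under detection the medians at 12 and 48 h were -0.06 and 0.07, and with camera and an estimated correlation the adjusted p values at these 4 times were 0.189, 0.27, 0.419 and 0.332. The RAP1 regulators passed at 144 h as higher (0.12, adjusted p = 0.0482; 0.379 with camera and 0.621 with an estimated correlation). The others were the oligodendrocyte list at 48, 96 and 144 h (0.0247, 1.41e-06 and 1.67e-07), the BMP list at 24, 48, 96 and 144 h (0.0247, 0.0072, 0.00448 and 0.0312) and the neuronal list at 144 h (0.0247) as higher. The ependymal list at 48, 96 and 144 h (0.0247, 0.00232 and 0.009), the FGF and ERK list (0.0215 and 0.00232) and the AhR and oestrogen receptor list (0.0269 and 0.0247) at 96 and 144 h passed as lower. Of these others, only the oligodendrocyte list at 96 and 144 h also passed with camera and an estimated correlation (0.00943 at both times). Camera at the preset correlation did not call the BMP list at 96 and 144 h (0.0536 and 0.216; 0.342 and 0.621 with an estimated correlation), the AhR and oestrogen receptor list at these times (0.104 and 0.147; 0.27 and 0.346) or the ependymal list at 144 h (0.0681; 0.31). With an estimated correlation the remaining calls had adjusted p values of 0.145 to 0.332.

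Among genes of the cell surface and matrix, Itga9, an integrin subunit, rose at 96 and 144 h (2.92 and 2.65), Itgb5 (-1.50) and Fermt2 (-0.59) fell at 96 h, and Tns3 (1.41) and Itgb8 (1.11) rose at 144 h, of 29 integrin and focal adhesion genes (smallest adjusted p = 0.104 at 6 h). Itgb5 was not called without 4-OHT A (0.0757) or B (0.0666) or vehicle B (0.108), Fermt2 without 4-OHT A (0.0759) or vehicle B (0.0861), Tns3 without 4-OHT A (0.0574) and Itgb8 without 4-OHT A (0.495) or vehicle C (0.382). Of 28 extracellular matrix genes 3 rose and 5 fell at each of the late times (smallest adjusted p = 0.22 at 144 h). Tnr, a tenascin, was at 1.62 and 2.26 and the laminin chains Lamb2 at -2.07 and -2.35 and Lama5 at -1.33 and -1.31, the last not called at 144 h without 4-OHT A (0.226) or vehicle C (0.19). Of 21 genes of cadherins and junctions 2 rose and 3 fell at 96 h and 3 rose and 3 fell at 144 h, among them Prkcz (1.80 at 144 h) up and Gja1 (-1.44 at 96 h) down (smallest adjusted p = 0.12 at 24 h).

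Of 24 neural stem cell markers 2 rose and 3 fell at each late time, with Sox9 (0.86 and 0.82) up and Slc1a3, Egfr and Gli2 (-1.38 and -1.12) down (smallest adjusted p = 0.286 at 12 h). At 144 h Sox9 was not called without 4-OHT A (0.313) or vehicle C (0.186), Slc1a3 without 4-OHT A (0.0963) and Egfr without either (0.32 and 0.255). Of 15 Wnt targets Fzd5 fell at both times (-1.35 and -1.08), at 144 h not without vehicle C (0.118), with 1 up and 1 down at 96 h and 2 up and 2 down at 144 h (smallest adjusted p = 0.164 at 12 h). Of 9 mesenchymal and pericyte markers Foxc1 (-1.84 and -2.10) and Prrx1 (-0.90 and -1.24) fell and Pdgfra, also on the oligodendrocyte list, rose (1.70 and 3.07), with a smallest adjusted p of 0.332 at 48 h. Prrx1 was not called without 4-OHT B (0.0526) or vehicle C (0.063) at 96 h or vehicle A (0.0616) at 144 h. Of 5 endothelial markers Emcn was at least 1.8-fold lower at 96 h, a call lost without any 1 of the 6 arrays (up to 0.098), and 0 were called at 144 h (smallest adjusted p = 0.0681 at 48 h). With 3 measured genes each, the Id family and the microglia markers were not tested as lists. Of the latter Cd14 fell by 1.14 at 96 h (adjusted p = 0.0439), a call lost without 4-OHT replicates A (0.195) or B (0.28) or vehicle replicates A (0.0709) or C (0.267), and Fcer1g and P2ry12 were not called at any time.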
